A study of Mus musculus with 6 samples.

How the data were processed

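RNA from whole pancreas of 8-week-old mice on a C57BL/6 background was measured on 6 Affymetrix arrays, 1 per mouse, from 3 mice without Rkip-1 and 3 wild-type mice of the same colony. Rkip-1 is the product of the gene listed as Pebp1 in current annotation. Samples were grouped by the genotype in the submitters' labels, which call the samples of a group biological replicates. These labels give neither the sex of the mice nor any batch, litter or scan date. The sample titles do not themselves state how many mice gave each sample. The knockout group is written KO and the wild-type group WT.

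The deposited values are on the log2 scale, 1 per probe set and array. They were made with RMA in the affy package, per the submitters' processing notes. RMA subtracts background, equalises the arrays' distributions and summarises the probes of each probe set, so a change shared by most genes cannot be seen in such values, and very bright probe sets are compressed near the top of the scale. Versions and settings of that step are not given in the sources used here. The table held 45101 probe sets, and its 6 columns were used with no further normalization in the main analysis. Column medians lay between 2.97 and 3.02 on the log2 scale, and the highest value of any tested probe set was 14.57. Raw scanner files were not analysed here, so no probe set has a detection call, and a fold against a level near the column medians is read as a lower bound. A fold against any level below the arrays' upper quartile of 4.53 can likewise be too small. The number of arrays limits the precision.

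Affymetrix control probe sets were left out of the tests, 64 in all, which left 45037. Of the 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none there. No gene was named from a probe set with several symbols. Symbols were brought up to date by Entrez identifier through a RefSeq gene table of mouse assembly GRCm38.p6 for 34754 probe sets, and 204 kept the symbol of the platform annotation. No genome build was given for the values, so no coordinates are printed, and the gene table served for names and for the order of neighbouring genes.

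Differences between genotypes were tested per probe set with lmFit and eBayes of limma 3.58.1 in R 4.3.3, as KO minus WT, two-sided, without covariates. P-values were adjusted by the method of Benjamini and Hochberg over the 45037 probe sets, and a probe set passed at an adjusted p under 0.05. A gene was represented by the brightest of its single-symbol probe sets over all 6 arrays, which gave 18193 genes. Fold changes carry 95% intervals from the moderated standard error, with 9.53 degrees of freedom. Comparisons of 1 value per array used exact two-sided permutation tests, in which 3 against 3 arrays cannot give a p below 0.1.

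Before the data were examined, 33 gene lists were fixed with 599 entries, 530 of them measured. They covered pancreatic cell types, other tissues that a dissection could carry over, the cell cycle, targets of the ERK pathway, stress and injury programmes, metabolism, and sex-linked genes. The sex-linked genes were read as values per array, and the other 32 lists were tested with camera of limma on 1 probe set per gene at its preset inter-gene correlation of 0.01. The adjusted p of a list is over these 32 lists. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed at the same time. It took Pebp1, the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap, 18 genes of islet, acinar, cell cycle and ERK biology whatever their result, up to 4 members of smallest p of each list past the threshold, and up to 2 of each other list described. Of the 18, 15 had a single-symbol probe set, and the rest, Ins1 and Amy2a5 among them, were not analysed here. Genes named outside this rule are said to have been chosen after their values were seen.

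Alternatives were a second quantile normalization, equal array medians, removal of dim probe sets, an intensity trend with robust variance, array weights, the replicate number as a block, leaving out each array in turn, the mean of all probe sets of a gene, removal of probe sets whose name suffix marks possible binding of several transcripts, 1 probe set per gene, an adjusted p under 0.1, and other tests of the lists. The Xist level as a covariate was added after seeing the data. The tests were also run on simulated data with 200 of 45037 probe sets changed. At 3 arrays against 3 they recovered 76% of changes of 1 log2 unit and 99% of changes of 2 log2 units, with 9 false calls among 184. Of 10 simulated lists of 20 genes shifted by 0.3, camera called 10, and it called 0 of 30 unshifted lists of independently varying genes. Figures were drawn with matplotlib 3.10.9.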

Results

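Gene expression in whole pancreas was compared between 3 mice lacking Rkip-1 and 3 wild-type mice, with 1 array per mouse. Rkip-1, encoded by Pebp1, holds back signalling through MEK and ERK. The title of the series names its role in the proliferation of pancreatic beta cells as the subject. Whole pancreas is mostly acinar tissue, and the islets that hold the beta cells are a small part of it. Array medians were 3.02, 3.02 and 3.01 for KO replicates 1, 2 and 3, and 3.01, 2.97 and 3.01 for WT replicates 1, 2 and 3, on the log2 scale. The 6 arrays correlated with each other at 0.989 to 0.993 over all tested probe sets. The mean correlation with arrays of the same genotype was 0.992 to 0.993, and with arrays of the other genotype 0.990 to 0.991.

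Pebp1 was low in every KO array. Its brightest probe set measured 6.03 ± 0.41 in KO and 9.88 ± 0.12 in WT (log2, mean ± SD, n = 3 each). This was a 14.4-fold lower level, with a 95% interval of 10.9 to 19.0 and an adjusted p of 5.05e-05. A second probe set fell from 8.52 ± 0.07 to 3.22 ± 0.42, a KO level near the array medians, so that the change of -5.30 on the log2 scale is a lower bound in size. Both probe sets carry name suffixes that mark sets able to bind more than 1 transcript, and the part of the gene removed in the knockout is not given in the labels.

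The largest changes in the KO pancreas were increases in genes of the Reg family, secreted C-type lectin-like proteins known from pancreatic injury and from defence against gut bacteria. Reg3g rose from 5.53 ± 1.02 to 12.21 ± 0.74, which was 103-fold (95% interval 48.8 to 216, adjusted p 0.000693). Reg3a rose from 6.47 ± 1.24 to 13.14 ± 0.20, a 102-fold change (48.6 to 214), and Reg3b from 8.56 ± 1.47 to 13.83 ± 0.11, a 38.4-fold change (16.2 to 91.2, adjusted p 0.00929). A second Reg3b probe set was higher by 6.20 on the log2 scale (adjusted p 0.00929), and the KO values of both lie near the compressed top of the scale. Reg3d, already abundant in WT at 11.32 ± 0.37, rose 3.90-fold to 13.28 ± 0.13 (3.01 to 5.04, adjusted p 0.00233). Reg2 measured 14.13 ± 0.03 in KO and 9.83 ± 1.84 in WT and did not pass (adjusted p 0.0826), although its groups did not overlap. Reg1 lay between 14.17 and 14.40 in all 6 arrays, near the top of the scale, where differences are compressed. Reg2 and Reg1 were singled out after their values were seen. The WT mice differed among themselves, and Reg3a measured 7.90 in WT replicate 1 against 5.76 and 5.74 in the other WT arrays.

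**Figure D1:**
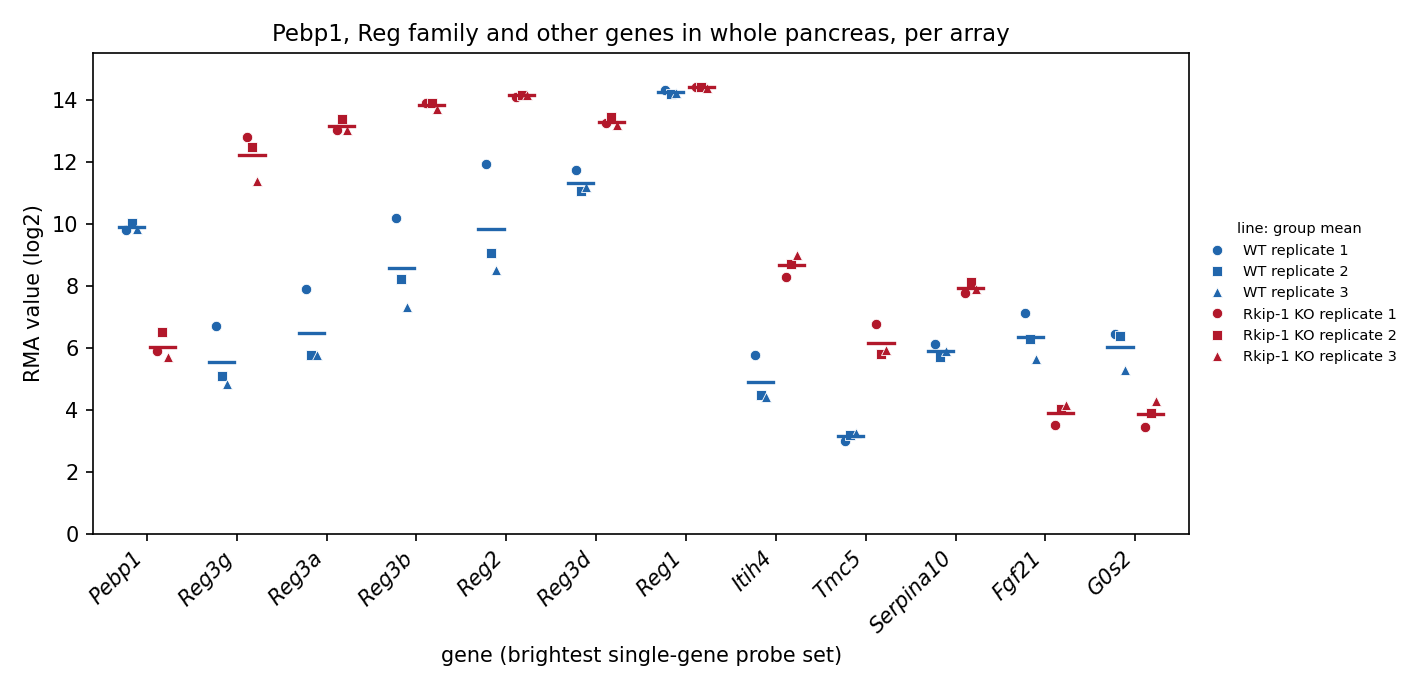
RMA values on the log2 scale for Pebp1, 6 Reg genes and 5 other genes, each symbol standing for 1 array and each line for a group mean of 3 arrays (blue WT, red Rkip-1 KO). Reg3g, Reg3a and Reg3b lie above 11 in every KO array and below 11 in every WT array, while Reg1 lies above 14 in all 6.

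Beyond the Reg genes, increases included plasma proteins best known from liver. Itih4, an acute phase protein, rose 13.6-fold from 4.89 ± 0.77 to 8.66 ± 0.36 (8.19 to 22.7, adjusted p 0.00277), and Serpina10, an inhibitor of coagulation proteases, rose 4.08-fold to 7.92 ± 0.18 (3.34 to 4.99, adjusted p 0.000435). Tmc5, of the transmembrane channel-like family, rose to 6.15 ± 0.52 from a WT level of 3.13 ± 0.14, near the array medians, so that the difference of 3.02 on the log2 scale is a lower bound (adjusted p 0.000693). Abcc3, an efflux transporter for organic anions, rose 2.68-fold, the stress-inducible Gadd45g 2.66-fold, and Dipk1a 2.58-fold, with adjusted p of 0.0097, 0.0248 and 0.0296. In each of these genes, as in the 4 Reg genes that rose, the 3 KO values lay above the 3 WT values, as the naming rule required. A further 9 genes that rose fell outside the naming rule and were chosen after their values were seen. They were B4galt1, Nfasc, F2 (prothrombin), Upk1b, Naprt, Wars (tryptophanyl-tRNA synthetase), Per1, Slc19a2 and Rhou. Their increases ran from 1.62-fold for Rhou to 2.54-fold for B4galt1, where that of Per1, from a WT level of 3.50, is a lower bound.

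Apart from Pebp1, 4 genes fell by their brightest probe set. Fgf21, a secreted metabolic hormone that acinar cells make, fell 5.46-fold from 6.33 ± 0.75 to 3.88 ± 0.35 (95% interval 3.32 to 8.97, adjusted p 0.0301). G0s2, an inhibitor of the lipase that opens triglyceride breakdown, fell 4.47-fold from 6.03 ± 0.66 to 3.87 ± 0.43 (2.78 to 7.17, adjusted p 0.0473). Asb11 fell 2.11-fold (adjusted p 0.024). Clec14a, a lectin of endothelial cells, fell by 0.81 on the log2 scale to a KO level of 3.31 ± 0.17, near the array medians, so that this is a lower bound in size (adjusted p 0.0362). In each of these genes the 3 KO values lay below the 3 WT values, as the naming rule required.

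In all, 44 probe sets passed the threshold, 33 higher and 11 lower in KO, and they named 31 genes. By the brightest probe set per gene, 24 genes passed, 19 higher and 5 lower. At an unadjusted p under 0.05, 3907 probe sets differed, against 2251.85 expected by chance. Splits of the arrays into equal groups that mixed the genotypes gave 1232 to 3500 such probe sets. Both groups of such a split held the genotypes in unequal numbers, so part of any genotype difference remained. Neither these counts nor the value of 2251.85 show how far a count can stray without a genotype difference. The real count was the highest, but the splits are too few for a share under 0.05. The groups did not overlap in 13.5% of probe sets, against 10% by chance, with no range over splits to compare. The 7 genes that passed at another probe set alone were chosen after their values were seen. Ankrd10 was higher by 2.24 on the log2 scale at one such probe set and 0.06 at its brightest, and Cnr1, a cannabinoid receptor, was higher by 2.16 and 0.12. Fads2 and Myo15b were higher too, and Rdx, Gm6958 and Trib3 were lower, Trib3 at -1.72.

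The number of changed probe sets was lower with an array left out. Among the counts were 24 without KO replicate 1, 18 without KO replicate 2, 26 without WT replicate 1 and 16 without WT replicate 2. The full range over the arrays left out is given further below. The count was 22 with the Xist level as a covariate, which was added after seeing the data. Fits with fewer arrays or a covariate have less power, so these falls need not come from particular mice. With each array left out in turn, 9 of the 24 genes passed every time, namely Pebp1, Reg3g, Reg3a, Reg3d, Itih4, Tmc5, Serpina10, B4galt1 and F2. Reg3b was lost without KO replicate 2 or WT replicate 2, Abcc3 without KO replicate 2, KO replicate 3 or WT replicate 2, and Wars without WT replicate 2, with adjusted p up to 0.0782, 0.0761 and 0.0707. Nfasc, Upk1b, Gadd45g, Fgf21, Dipk1a, G0s2, Asb11, Naprt, Per1 and Slc19a2 were each lost with 3 to 5 of the 6 arrays left out, with adjusted p up to 0.284. Clec14a and Rhou were lost in all 6, with adjusted p up to 0.231 and 0.232. With the mean of all probe sets of a gene, Clec14a differed by -0.41, Upk1b by 0.46 and Slc19a2 by 0.45 on the log2 scale, against -0.81, 0.99 and 0.77, and none of the 3 passed. Over all alternatives their adjusted p ran from 0.0297 to 0.323, from 0.0096 to 0.157 and from 0.0262 to 0.284. A variance model with an intensity trend and robust estimation, which gives less shrinkage to genes that vary strongly within groups, left Reg3g, Reg3a, Reg3b and Itih4 at adjusted p of 0.16, 0.16, 0.276 and 0.0704. Over all alternatives, the adjusted p of Reg3g ran from 1.15e-05 to 0.16, that of Reg3a from 9.59e-08 to 0.16, that of Reg3b from 1.40e-05 to 0.276, and that of Itih4 from 4.39e-05 to 0.0704. Fgf21 and G0s2 were lost in the same model and with the Xist covariate, with log2 differences from -2.80 to -2.06 and from -2.54 to -1.94 over all alternatives.

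The endocrine and acinar products of the pancreas showed small differences, none past the threshold. Insulin (Ins2) measured 12.61 ± 0.08 in KO and 12.69 ± 0.02 in WT, a log2 difference of -0.07 with a 95% interval of -0.27 to 0.12. Glucagon (Gcg) differed by -0.15, somatostatin (Sst) by -0.13, pancreatic polypeptide (Ppy) by -0.30 and amylin (Iapp) by -0.14. Pdx1, a transcription factor of beta cells, measured 5.13 ± 0.16 in KO and 4.66 ± 0.32 in WT (adjusted p 0.426). The acinar enzymes Cpa1, Ctrb1 and Cel lay between 14.26 and 14.39 in all arrays, at the top of the scale, where a difference could be hidden. Of the cell cycle and ERK genes, Mki67 differed by -0.52 (95% interval -1.26 to 0.23), Ccnd1 by -0.26, Ccnd2 by -0.86, Cdkn1a by -0.89, Dusp6 by -0.17 and Egr1 by -1.10. By limma, 0 of these 15 always-named genes passed, and 5 had an unadjusted p under 0.05, with Pdx1 higher and Ppy, Ccnd2, Cdkn1a and Egr1 lower.

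Several gene groups were lower in KO by small amounts spread over many members. Of the 32 lists tested with camera at its preset correlation, 7 passed, 6 of them lower and 1 higher in KO. With an estimated correlation 0 of the 32 passed and 3 had an unadjusted camera p under 0.05. These were the G1 (0.0254), acute phase (0.0266) and other islet (0.038) lists. The matrix, unfolded protein response, S phase and G2 and M phase lists had estimated correlations of 0.254 to 0.431. Their unadjusted camera p was then 0.1355 to 0.2374. Fry, which asks whether a list's genes move one way on balance, passed 0, with 4 at an unadjusted p under 0.05. These were the same 3 lists and that of described Pebp1 partners, and 10 lists passed fry's test for change in either direction. In the lower lists, 0 members passed over all genes by their brightest probe set. Arrays with high Xist were unequally spread over the genotypes, with 2 of 3 in KO and 1 of 3 in WT.

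**Figure D2:**
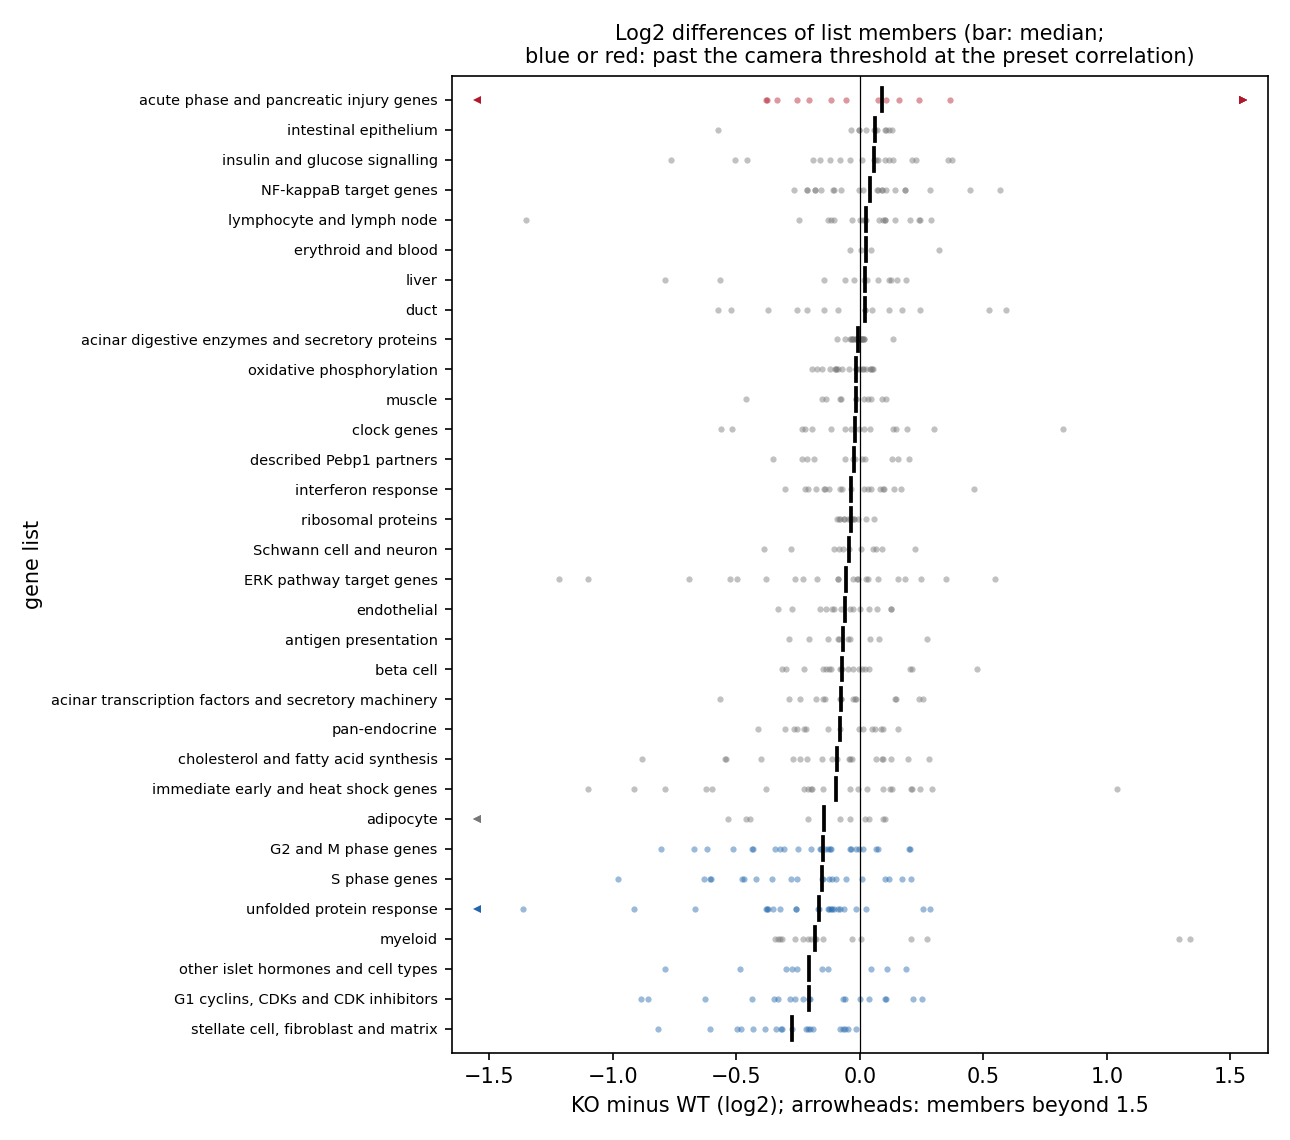
Log2 differences (KO minus WT) of the measured members of 32 gene lists, 1 dot per gene by its brightest probe set, with a black bar at each list's median and overlapping arrowheads for members beyond 1.5. Lists in blue or red passed camera at the preset correlation, the stellate cell, fibroblast and matrix list having the lowest median at -0.28.

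Genes of DNA replication and cell division were lower in KO. In the S phase list 16 of 21 measured members were lower, with a mean log2 difference of -0.25 and adjusted p of 0.00091 (adjusted p of 0.839 with an estimated correlation). Adjusted over the list alone, 6 of them passed, among them the replication clamp Pcna at -0.47, the helicase subunits Mcm5 at -0.98 and Mcm6 at -0.61, and the licensing factor Cdt1 at -0.63. In the G2 and M phase list 21 of 26 were lower, with a mean of -0.20 and adjusted p of 0.00325 (adjusted p of 0.839 with an estimated correlation). Ccnb2, at -0.67, was the 1 member that passed when adjusted over the list alone, and Cdc20 measured -0.25, Ccna2 -0.62 and Top2a -0.43. Without KO replicate 2 this list was no longer past the threshold, with a mean of -0.10 and adjusted p of 0.0818, and without WT replicate 1 its adjusted p was 0.0576, in a range over all alternatives from 0.000167 to 0.839. In the list of G1 cyclins, CDKs and CDK inhibitors 13 of 19 were lower, with a mean of -0.22 and adjusted p of 0.00817 (adjusted p of 0.406 with an estimated correlation). Its 2 members past the threshold when adjusted over the list alone act in opposite directions on the cycle, Ccnd2 as a cyclin and Cdkn1a as an inhibitor. Cdkn1c, another inhibitor, measured -0.44 and Ccnd3 -0.28.

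The unfolded protein response list, which serves protein folding in the endoplasmic reticulum, was lower in 22 of 25 members, with a mean of -0.34, a median of -0.17 and adjusted p of 5.78e-05 (adjusted p of 0.839 with an estimated correlation). Adjusted over the list alone, 5 passed. Chac1, which degrades glutathione, measured 7.83 ± 1.08 in KO and 10.45 ± 0.62 in WT, a difference of -2.63. Trib3 differed by -1.36, Ddit3 (CHOP) by -0.91 and Herpud1 by -0.67. The adjusted p over all genes was 0.0614 for Trib3, which passed at another probe set, and 0.142 for Chac1.

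**Figure D3:**
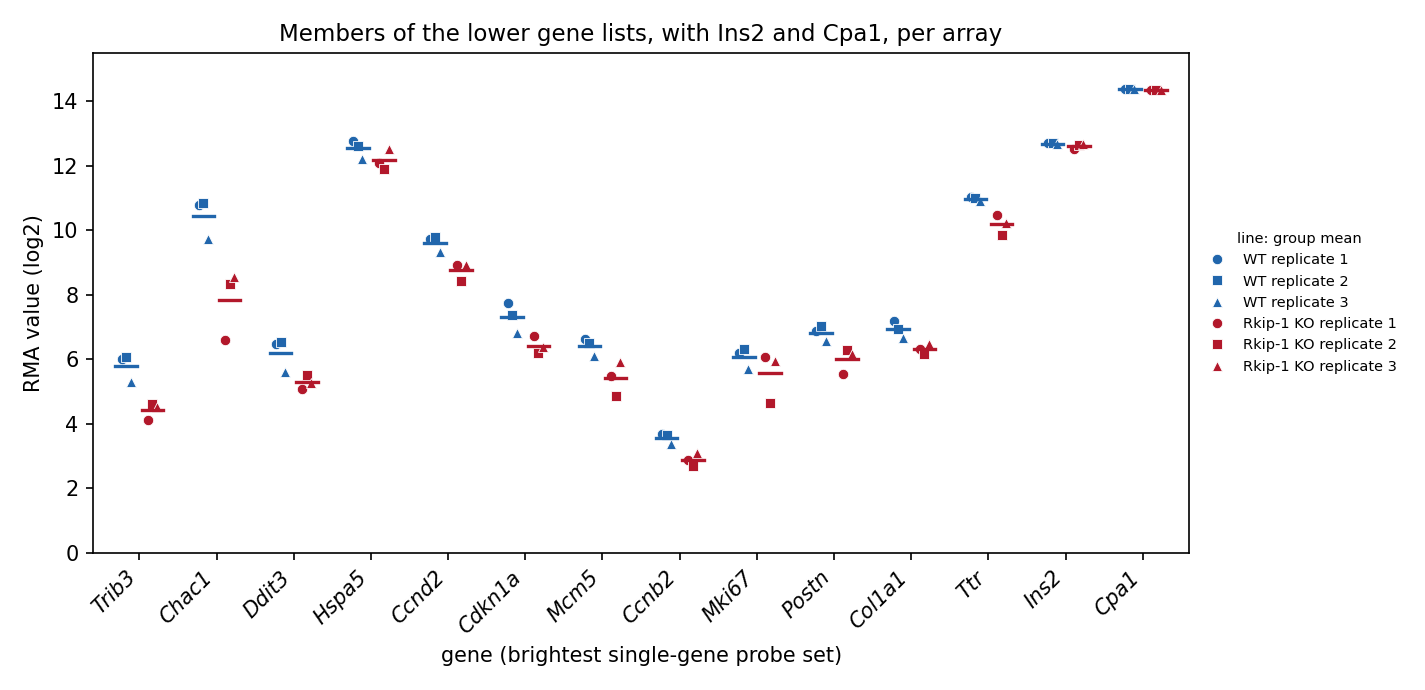
RMA values on the log2 scale for members of the lists that were lower in KO, with Ins2 and Cpa1 beside them, each symbol standing for 1 array and each line for a group mean of 3 arrays. Chac1 has means of 10.45 in WT and 7.83 in KO, while Ins2 differs by -0.07 (KO minus WT).

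Markers of stellate cells, fibroblasts and matrix were lower in 19 of 19 members, with a mean of -0.29 and adjusted p of 1.95e-05 (adjusted p of 0.839 with an estimated correlation). Postn measured -0.82, Col1a1 -0.61, Col3a1 -0.50 and Col1a2 -0.43, and these 4 passed when adjusted over the list alone. Without KO replicate 1 the mean was -0.16, with an adjusted p of 0.00817, in a range over all alternatives from 1.26e-07 to 0.839. The fat list did not pass, with a mean of -0.47 and adjusted p of 0.213, and its mean was -0.06 without KO replicate 1. The list of other islet hormones and cell types was lower in 7 of 10, with a mean of -0.20 and adjusted p of 0.0108 (adjusted p of 0.406 with an estimated correlation). Its 2 members past the threshold when adjusted over the list alone were Ttr, a thyroid hormone carrier of alpha cells that liver also makes, at -0.79, and the gut and islet peptide Pyy at -0.49. Hhex, of delta cells, measured -0.28. This list was no longer past the threshold without KO replicate 1, WT replicate 2 or WT replicate 3, with adjusted p of 0.121, 0.0631 and 0.0532, in a range over all alternatives from 0.000186 to 0.406.

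The acute phase and pancreatic injury list was higher, with 10 of 18 members higher, a mean of 1.20, a median of 0.09 and adjusted p of 0.00817 (adjusted p of 0.406 with an estimated correlation). The gap between mean and median reflects a few large differences. Over all genes Reg3a, Reg3b, Reg3d and Reg3g rose and Fgf21 fell, and adjusted over the list alone Reg2 passed as higher and Cd44 as lower. Without WT replicate 3 its adjusted p was 0.0532, in a range over all alternatives from 4.40e-05 to 0.406.

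The other 25 lists did not pass by camera, the lowest adjusted p among them being 0.177. The ERK target list, the readout nearest to the known action of Rkip-1, had 14 of 22 members lower and 8 higher, a median of -0.06 and adjusted p of 0.242 by camera. It was among the 10 lists that passed fry's test for change in either direction, with an adjusted p of 0.0187. The other 9 were the acute phase, G1, other islet, clock, duct, insulin signalling, NF-kappaB, immediate early and acinar transcription factor lists. Adjusted over the list alone, 3 of its members passed as lower and 1 as higher, with Myc at -0.50 and Phlda1 at -0.69. Beta cell genes had a median of -0.07 over 19 members and adjusted p of 0.481, and pan-endocrine genes a median of -0.08 and adjusted p of 0.177, which was 0.0186 without WT replicate 1, in a range over all alternatives from 0.0186 to 0.839. Acinar digestive enzymes had a median of -0.01 over 22 members and adjusted p of 0.874, and acinar transcription factors and secretory machinery a median of -0.08 and adjusted p of 0.481, with Ptf1a at -0.56 and Xbp1 at 0.25. The list of described Pebp1 partners, MEK and ERK among them, had a median of -0.02 and adjusted p of 0.481.

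Signs of RNA quality were close between genotypes. The 3' minus 5' log2 difference of Actb averaged 1.89 ± 0.13 in KO and 1.89 ± 0.11 in WT (exact permutation p of 1), and that of Gapdh 0.93 ± 0.10 and 0.82 ± 0.18 (exact permutation p of 0.5), where the smallest p possible is 0.1. Xist, transcribed from the inactive X chromosome of females, was high in KO replicate 2, KO replicate 3 and WT replicate 3, at 9.09 to 9.79, and low in the others, at 4.44 in KO replicate 1 and 4.30 in WT replicate 1, with WT replicate 2 lowest. The Y-linked genes Eif2s3y, Kdm5d and Uty ran the other way.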

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

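The test below was fixed before its result was seen. The bacterial hybridisation controls bioB, bioC and bioD, which take no part in the comparison of genes, were brighter in the KO arrays. Their mean over 14 probe sets was 10.43 ± 0.08 in KO and 10.21 ± 0.08 in WT, a difference of 0.228 on the log2 scale (exact permutation p of 0.1, the smallest that 3 against 3 arrays can give). In 12 of the 14 probe sets the 3 KO values exceeded the 3 WT values. The cre controls, brighter still, differed by 0.04 (exact permutation p of 0.3). The 1593 other probe sets of the same brightness had a median difference of -0.0474, which decides nothing about an offset shared by all probe sets of that brightness, since RMA equalises the arrays and holds such a median near 0. These transcripts are added to the sample before hybridisation and have no source in the pancreas. Such an offset before normalization stays open, as does a difference in the amount of sample or of control added to each array, which was not tested, and no biological explanation was tested.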

How the results depend on the processing

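The Xist covariate was chosen after seeing the data, the other alternatives before. Against 44 changed genes counted as probe sets, some counts moved by over 1.5 times. Such counts were 76 at an adjusted p under 0.1 and 23 with the mean of all probe sets of a gene. Without probe sets whose suffix marks possible binding of several transcripts the count was 25, and with the brightest probe set per gene 24. Fewer features were tested in the last 3 of these settings. The count was 22 with the Xist covariate, and from 16 to 41 with each array left out. It was 39 to 50 under the remaining alternatives other than the replicate block, and a variance model with trend and robust estimation shared 35 of its 49 calls with the 44. The labels do not say that replicate numbers pair the mice. Same-numbered arrays correlated at 0.26, -0.03 and -0.09 in their deviations from the group means, and differently numbered ones at -0.222 to 0.245. On the second axis of a principal component analysis (23.1% of the variance), KO replicate 1 at 25.97 and WT replicate 1 at 20.33 lay apart. The other arrays lay between -17.2 and -8.0. These values do not settle whether same-numbered arrays shared a batch. With the replicate number as a block, 33 probe sets passed, 29 of them among the 44, and 9 lists. Against 7 gene lists past the threshold, 0 passed with an estimated correlation and 0 with fry, which allow for genes of a list varying together, and from 5 to 9 passed with each array left out. The Pebp1 log2 difference stayed past the threshold under every alternative that measured it, from -4.57 to -3.68. With the probe sets of such a suffix removed, Pebp1 had no probe set left. Of 378 alternative values of the 24 genes past the threshold, 283 stayed past it. The remaining 95 kept their direction but no longer passed, and 0 reversed. Of 126 values for the 7 lists, 104 stayed past the threshold and 22 kept their direction but no longer passed. The mean of the lymphocyte and lymph node list reversed to 0.11 without KO replicate 1, in a range from -0.13 with each array left out. That of the myeloid list reversed to -0.18 without KO replicate 2, in a range up to 0.28, and to -0.10 with the Xist covariate. These lists passed in those settings alone, and the cause was not tested. A further 32 sign changes were in values past the threshold in neither setting. Signal over background could not be judged without scanner files.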

Other observations

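The tests on intestinal tissue, liver tissue, the sexes of the mice and the arms of the unfolded protein response were chosen only after the result was seen. Further groups, which did not pass by camera, gave a broader view of the tissue. Fat markers were lower in 8 of 12 members, with Cd36 at -0.53 and Lpl at -0.46, and a list adjusted p of 0.213. Car3 at -2.58 and Adipoq at -1.51, singled out after their values were seen, had adjusted p of 0.716 and 0.655. Both were far lower in KO replicate 1, at 2.51 and 2.26, than in the other 5 arrays, at 9.19 or more and 5.12 or more. The fat list passed without KO replicate 2 (adjusted p 0.0182) and without WT replicate 1 (0.00895), in a range over all alternatives from 0.00612 to 0.903. Duct genes went both ways, with the mucin Muc1 at 0.59 and Sox9, a duct transcription factor, at 0.52, and with Car2 at -0.37 and Anxa3 at -0.52, these 2 chosen after their values were seen. None of the 4 passed over all genes, and the list adjusted p was 0.999. Clock genes went both ways as well. Per1 rose by 0.82 over all genes, Nfil3 measured -0.56, and the list adjusted p was 0.874. In insulin and glucose signalling Pik3r1 was at -0.50 and Igf2 at -0.46 (list adjusted p 0.799), and in immediate early and heat shock genes Jun was at -0.91 and Ier2 at -0.62 (0.311). NF-kappaB targets had Bcl3 at 0.57 and Rela at 0.44 (0.655), and cholesterol and fatty acid synthesis had Scd2 and Srebf1 both at -0.54 (0.29, and 0.0338 without KO replicate 3, in a range over all alternatives from 0.0338 to 0.839). Adjusted over the list alone, 1 duct gene passed as higher, 2 clock genes as higher and 1 as lower, and in insulin signalling, as in immediate early genes, 1 as higher and 3 as lower.

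The remaining lists had adjusted p of 0.311 for lymphocytes, myeloid cells and oxidative phosphorylation, 0.481 for endothelium, intestine, ribosomal proteins and blood, 0.547 for muscle, 0.705 for antigen presentation, 0.782 for Schwann cells and neurons, and 0.797 for the interferon response and liver. Without 1 array, 3 of them passed, lymphocytes without KO replicate 1 (0.0237, in a range over all alternatives from 0.0237 to 0.936), myeloid cells without KO replicate 2 (0.0339, from 0.0278 to 0.839) and oxidative phosphorylation without WT replicate 1 (0.0186, from 0.0186 to 0.94). In 5 lists the mean, the median and the direction of the test differed in sign. These were lymphocytes (median 0.03, mean -0.02, test up), myeloid cells (-0.18, 0.02, down), liver (0.02, -0.07, down), insulin and glucose signalling (0.06, -0.03, down) and duct (0.02, -0.03, down). Among myeloid genes the neutrophil genes S100a8 and S100a9, singled out after their values were seen, measured 1.34 and 1.29 with adjusted p of 0.726 and 0.633, and SDs among KO arrays of 2.24 and 1.72. In this list 12 of 17 members were lower.

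Reg3a, Reg3b, Reg3g, Reg3d and Reg2 were higher in KO by a mean log2 difference of 4.98, though Reg2 did not pass. Intestine also makes Reg3 genes, and intestinal tissue in the KO dissections is argued against by the intestinal epithelium list, whose mean difference was 0.00462 ± 0.0548 (SE over 12 members). The highest members of this list stayed low, Krt20 at 4.36 in KO and 4.94 in WT and Tff3 at 4.04 and 3.93, and of its 12 members 1 is also in the duct list and 1 lay above the upper quartile of all probe sets in WT. Uneven sexes are argued against as the whole cause, since with the Xist level as a covariate the mean difference was 5.24. Its SE over the 5 genes, 0.92, gives the spread between these genes and not the uncertainty over mice. An effect of the genotype stays open beside litter and housing, which the labels do not describe and which were not tested. Inflammation is not described there either. Over all 6 arrays the NF-kappaB, myeloid and lymphocyte lists did not pass by camera, with adjusted p of 0.655, 0.311 and 0.311. The list of IL-6 and STAT3 target genes described below was higher, so inflammation stays open as well.

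The proliferation, unfolded protein response and matrix lists were lower together, with a median difference of -0.20 over 110 members. Uneven sexes are argued against as the whole cause, since the median was -0.183 with the Xist covariate. An offset between the groups that depends on brightness stays open, since RMA holds the medians of brightness bins near 0, here from -0.07 to 0.05, and the members' median of -0.185 relative to them decides nothing. The 10 splits of the 6 arrays are too few to give a share under 0.05, and the real split passed 7 lists, the highest other 11, and 4 splits passed 7 or more, among them the split that parts the 3 arrays with high Xist from the rest. The splits that mix the genotypes also keep part of any genotype difference, so their counts do not show what variation between mice alone would give. Variation between mice shared by the members of a list therefore stays open beside an effect of the genotype. For the matrix list, so does less fat and connective tissue in the dissection of KO replicate 1, without which its mean was -0.16.

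For changed probe sets, the 10 splits are likewise too few for a share under 0.05. Those that mix the genotypes again keep part of any genotype difference. The real split gave 44 and the highest other 9, for the arrays with high Xist against the rest, and 1 split, the real one, gave 44 or more.

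A hypothesis for the rise of the Reg3 genes is IL-6 and STAT3 signalling, which is known to induce them. A list of 23 target genes, with Stat3, the Reg genes and Itih4 left out, had a mean difference of 0.231 ± 0.0885 (SE over members) and was higher by camera (p of 0.000838, and p of 0.021 with an estimated correlation, neither adjusted over the 5 such lists tested). Fgl1 was at 1.43 and Socs3, a feedback inhibitor of STAT3 induced by it, at 1.40. By limma 0 of the 23 passed over all genes, and 8 had an unadjusted p under 0.05, of which 7 were higher. A higher list is what the hypothesis predicts, in the same mice, although 9 of the 23 were lower. The acute phase genes Hp and Saa2 measured -0.04 and 0.17. These 2, like Lbp, Orm1, A2m, Orm2 and Saa1, lay below the upper quartile of 4.53 in KO and WT, where differences can appear too small. Their small differences therefore count little for or against the hypothesis.

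Itih4, Serpina10 and F2 are made in liver. Liver tissue in the KO dissections is argued against by the liver list, with a mean difference of -0.074 ± 0.0869 (SE over 12 members), 1 of them also in an islet list and 2 above the upper quartile of all probe sets in WT. Albumin (Alb) measured 4.12 in KO, 0.12 above WT, Tat 4.86 and 4.74, and Ttr, which islets also make, 10.19 and 10.98.

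PPAR-alpha induces Fgf21 and G0s2 in liver, and a lower activity of it was tested as a hypothesis for their fall. The 19 other PPAR-alpha targets measured had a mean difference of -0.00391 ± 0.043 (SE over members). Ppargc1a, Plin2 and Ehhadh were at -0.44, -0.26 and -0.27 with unadjusted p under 0.05 by limma. Several members, Cyp4a14, Vnn1 and Pdk4 among them, lay below the upper quartile of 4.53 in both groups, where a fall could be hidden. Among brighter members Cpt1a at -0.01 and Cpt2 at -0.02 differed little, while Plin2 and Ehhadh were lower. The list mean therefore does not decide the question. DNA flanking Pebp1 from the strain in which the knockout was made could bring differences of its own. Among the 50 measured genes nearest to Pebp1, 5 had an unadjusted p under 0.05, against a median of 5 in other runs of 50 neighbours (permutation p of 0.578, one-sided), and 0 passed by limma over all genes. This argues against flanking DNA as a source of many differences near the gene, and not against single variants.

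Whether the ATF4 and CHOP arm alone accounts for the lower unfolded protein response list was left open. Its 8 genes had a mean difference of -0.80 ± 0.302 and the 15 genes of the chaperone arm -0.15 ± 0.0452, a difference between arms of -0.656 ± 0.306 (SE over members). By camera the unadjusted p was 1.61e-08 for the ATF4 and CHOP arm and 0.0125 for the chaperone arm. With an estimated correlation the camera p was 0.0731 and 0.456. The chaperone arm was lower in 13 of 15 members, yet 0 passed by limma and 0 had an unadjusted p under 0.05. Whether this arm shifted as well is thus uncertain, which keeps the question open.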
